A study of Arabidopsis thaliana with 5 samples.

How the data were processed

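The series holds 5 samples from 10 day old seedlings of the Col-0 accession: a ChIP library and an input for each of the tagged histones HTR5 and HTR13, and 1 RNA library that was not analysed here. Groups were taken from the sample titles, with 1 library per group. The ChIP libraries were made with an anti-Myc antibody and sequenced on an Illumina instrument, per the labels' protocols. Reads were mapped with Bowtie, per the submitters' processing notes. The Bowtie version, its settings and the genome build are not given in the sources used here.

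Each deposited file lists read alignments, 1 per line, as chromosome, strand and position, with no header, no sequence and no mismatch count. No chromosome, strand and position was listed more than once in any library, so repeated reads had been reduced to 1 per position before deposit. Positions were read as the 0-based leftmost base of the read on both strands. The chloroplast inverted repeat held no reads (a gap of 26229 positions in the inputs), so only reads with a unique place were listed, and the edges of the gap gave a read length of 36 bases. Coordinates of intervals printed in the text are 1-based, and the highest positions given next are 0-based. The numbers of reads per region were counted from these deposited lines.

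The highest positions in the files were 30432521 on chromosome 1, 19705023 on chromosome 2, 23470769 on chromosome 3, 18585006 on chromosome 4 and 26992692 on chromosome 5. Those of chromosomes 1, 2, 3 and 5 lie beyond the chromosome ends of the assembly behind the gene table at hand (TAIR10.1), as far as is known from general knowledge. The table was therefore used only for names, chromosomes and gene order, and none of its coordinates were set against the reads. For this reason the planned comparisons over annotation classes, gene bodies, single genes, gene lists (housekeeping, ribosomal protein, photosynthesis, Polycomb target, seed, pollen, heat, resistance and histone H3 genes), and named genes were not made, and no genome sequence was used for repeats, telomeres or GC content. Reads with 0 mismatches and reads with other alignments could not be separated, and counting identical positions once changed nothing because the files already do so.

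Each read was placed at its 5' end moved 75 bp in its own direction and counted in 1 kb bins. Enrichment was log2 of ChIP over input, with 1 read added to each count and each library scaled to its alignments on chromosomes 1 to 5. D is the enrichment of HTR5 minus that of HTR13. Bins with fewer than 20 reads in either input were left out of bin counts. Regions were measured from summed reads, with exact conditional binomial intervals for an enrichment and a normal approximation on the log scale for D, at the 95% level. These cover counting error only. The log2 ratio of the HTR5 input over the HTR13 input was computed in the same way as background. No test between conditions was made.

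The centromere point of a chromosome was the middle of the 1 Mb window, in steps of 100 kb, with the fewest reads in both inputs. This replaced a rule on gene cover and was chosen after the files had been seen. The points were at 14.9, 3.6, 13.7, 4.2 and 11.7 Mb of chromosomes 1 to 5. The pericentromere is the part within 2 Mb of a point, the arms are the rest, and chromosome ends are the first and last 50 kb. The blocks, their edges, the distance classes, the classes by unmappable positions, their split by distance, and the 10 kb windows and segments were also chosen after the files had been seen. Start positions in runs of 30 or more with no read in any library on either strand were called unmappable. They made up 23.1% of the pericentromeres and 3.71% of the arms.

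Because only 1 read per position and strand was listed, the counts saturate. The inputs filled 41.0% and 40.8% of the mappable nuclear start positions, the HTR5 ChIP 39.3% and the HTR13 ChIP 34.2%. This compresses ratios. A correction for positions already taken, -m ln(1 - x/m) for x reads on m mappable starts of a 1 kb bin, was added as an alternative. The measure was tested on simulated data made on the real 1 kb bins: for a simulated D of 2 in 200 bins the median was 1.50 without the correction and 2.04 with it, and 99.5% of the bins passed the threshold of 1 without it. For a simulated D of -1.5 in 200 bins, 76% passed the threshold without it. Among 109398 bins with no simulated difference 3 passed it. A simulated regional D of -1 was measured as -0.76 without the correction and -0.99 with it. Saturation was also simulated without any D, with both ChIPs raised 4-fold near the points and the HTR5 ChIP at 4 times its depth, as a check that the correction can end a difference made by saturation. In the simulations with a known D, the measured D was nearer to 0 than the simulated one, and the values of D in the text are read in the same way.

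Differences between the inputs were searched in bins of 500 bp with at least 200 reads in each input and at least 800 mappable starts, with the correction applied. The alternatives tried, most of them fixed before the data were examined, were no shift, no input, the input of the other line, scaling to the median of 10 kb bins, 10 reads added, minimums of 100 reads and of 0, a pericentromere of 1 Mb, 50 kb bins, a threshold of 0.5, and leaving out each chromosome in turn. The correction for taken positions, fully mappable bins alone, bins with under 25% of at least 500 mappable starts taken in both inputs, and another rule for the centromere points were added later. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9.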

Results

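Chromatin was profiled in 10 day old Arabidopsis thaliana seedlings of the Col-0 accession, to map where the histone H3 variants H3.3 and H3.1 lie in the genome. H3.3 was followed through HTR5 (AT4G40040) and H3.1 through HTR13 (AT5G10390). H3.1 is the variant assembled into chromatin at DNA replication, and H3.3 is the variant that can be incorporated outside replication. Each protein was recovered with an anti-Myc antibody. Every ChIP library had its own input, a library of genomic DNA that serves as its control. Each of the 4 groups held 1 library, so no value below has a replicate check and no test between conditions was made. The HTR5 ChIP held 87054216 distinct alignments on the 5 nuclear chromosomes, and the HTR13 ChIP held 75847226. The inputs held 90857500 for HTR5 and 90483249 for HTR13. Intervals given below are 95% intervals from read counts and cover counting error only. The polyadenylated RNA library of the series was not analysed here.

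Enrichment is the log2 ratio of ChIP to input after each library is scaled to its nuclear alignments, and D is the enrichment of HTR5 minus that of HTR13. A value of 0 is therefore the library average, and a gain in one part of the genome is balanced by a loss elsewhere. The deposited positions carry no build name, and positions below are in the coordinates of the files.

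The first comparison was between the regions around the centromeres and the chromosome arms. Around the centromeres HTR13 was enriched and HTR5 was depleted. Within 2 Mb of the centromere points, HTR13 reached 1.46-fold of its input (log2 0.55, interval 0.55 to 0.55), and HTR5 was at 0.813-fold (log2 -0.30, interval -0.30 to -0.30). D in this part was -0.85. In the arms the order was the opposite, with HTR5 at 1.03-fold of its input and HTR13 at 0.933-fold, and D at 0.14. As the 2 parts make up the whole, these summed arm values follow from those of the pericentromeres. Between the pericentromeres and the arms, D differed by -0.98. The inputs differed far less: log2 of the HTR5 input over the HTR13 input was -0.08 in the pericentromeres and 0.01 in the arms. D in the arms was 0.07 when the arms began 1 Mb from the points, and also 0.07 when only fully mappable bins were used and scaled among themselves.

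All 5 chromosomes showed the same arrangement. HTR13 enrichment in the pericentromere ranged from 0.49 on chromosome 4 to 0.61 on chromosome 3, and HTR5 enrichment from -0.37 on chromosome 3 to -0.24 on chromosome 4. D in the pericentromere was -0.80 on chromosome 1, -0.85 on chromosome 2, -0.98 on chromosome 3, -0.73 on chromosome 4 and -0.85 on chromosome 5. With points placed by unmappable positions, that of chromosome 4 moved by -0.5 Mb and the others by at most 0.1 Mb. The weaker values of chromosome 4 may thus depend on where its window lies. D in the arms lay between 0.09 on chromosome 2 and 0.16 on chromosome 5. Among 200 bins of 100 kb in the pericentromeres, D was below 0 in 197, with a median of -0.96 and quartiles of -1.15 and -0.72. Among 994 such bins in the arms, D was above 0 in 781, with a median of 0.18 and quartiles of 0.03 and 0.29. The log2 ratio of the inputs had the same signs nearly as often, below 0 in 192 pericentromeric bins and above 0 in 738 arm bins. Its medians were only -0.09 and 0.01, so the size of D, and not its sign, sets it apart from the inputs.

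**Figure D1:**
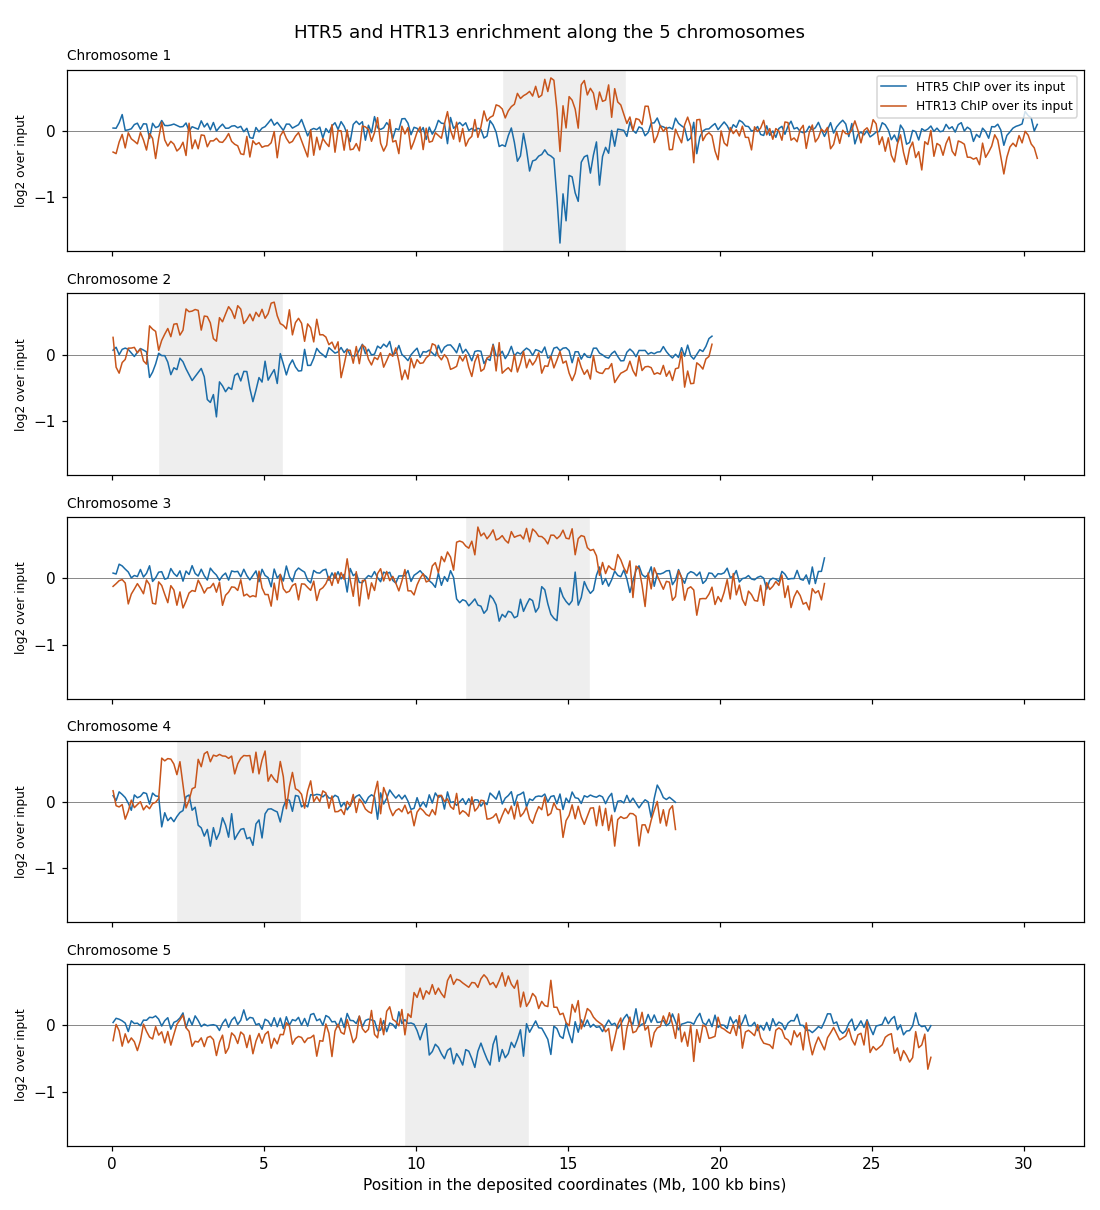
Enrichment over input (log2) of HTR5 and HTR13 in 100 kb bins along the 5 chromosomes, against position in Mb. The grey bands mark 2 Mb on either side of each centromere point, where HTR13 lies above 0 and HTR5 below 0 in most bins.

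Values were then summed over the 5 chromosomes by distance from the centromere points. HTR13 enrichment was 0.62 in the first 0.5 Mb from the centromere points, 0.56 at 1 to 1.5 Mb, 0.41 at 1.5 to 2 Mb and 0.23 at 2 to 3 Mb. It was -0.02 at 3 to 5 Mb, -0.13 at 5 to 10 Mb and -0.21 beyond 10 Mb. HTR5 enrichment was -0.47 in the first 0.5 Mb, -0.30 at 1 to 1.5 Mb and -0.03 at 2 to 3 Mb, and then stayed between 0.04 and 0.05 further out. In the arms, HTR13 thus continued to decline with distance while HTR5 was nearly level. The log2 ratio of the inputs went from -0.10 near the points to 0.01 in the outer arms. These sums hide steps on single chromosomes, which lie at different distances.

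**Figure D2:**
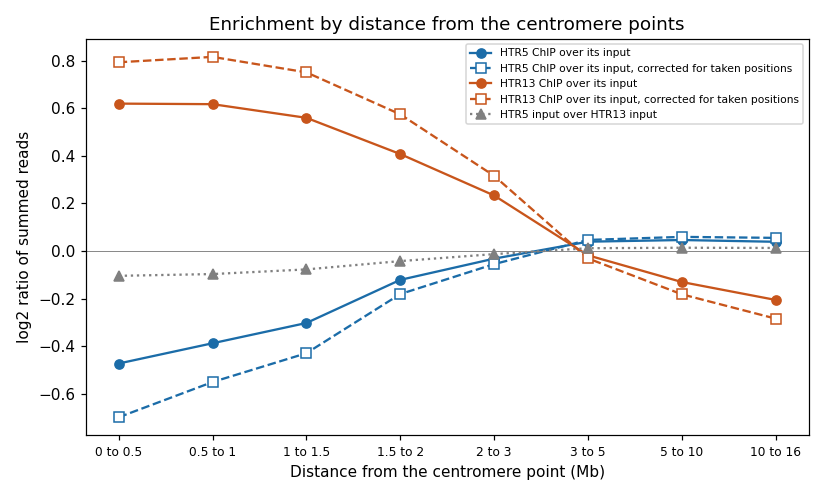
Enrichment over input (log2) of HTR5 and HTR13 from summed reads, by distance from the centromere points in Mb. Open squares with dashed lines are the values after correction for positions already taken, and grey triangles are the ratio of the inputs, which goes from -0.10 to 0.01.

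Runs of at least 3 neighbouring 100 kb bins with D of -0.5 or lower formed 11 blocks with a summed length of 17.7 Mb. Of these, 6 held no centromere point, and 5 did, 1 on each chromosome. The latter covered 13.2 to 15.9 Mb of chromosome 1, 2.4 to 5.5 Mb of chromosome 2, 11.3 to 15.2 Mb of chromosome 3, 2.8 to 5.1 Mb of chromosome 4 and 10.4 to 13.4 Mb of chromosome 5. D over these blocks ranged from -1.07 on chromosome 4 to -0.98 on chromosome 1. At their 10 edges, D differed between the neighbouring bins inside and outside by -0.82 to -0.25, with a median of -0.53. Part of this follows from the rule that sets the edges. At 15.9 Mb of chromosome 1, 5.5 Mb of chromosome 2 and 15.2 Mb of chromosome 3, a single bin preceded another block. The edge at 15.2 Mb of chromosome 3 had the largest step, -0.82. The steps at these edges thus do not measure how sharply the low D ends. A separate block lay on the short arm of chromosome 4, from 1.6 to 2.3 Mb. This arm carries a heterochromatic knob in the Col-0 accession. HTR13 enrichment was 0.59 across the block and HTR5 enrichment -0.25, with D at -0.84 (interval -0.84 to -0.83). Before it, from 0 to 1.6 Mb, D was 0.12. After it D was -0.39 from 2.3 to 2.4 Mb, 0.12 from 2.4 to 2.6 Mb and -0.31 from 2.6 to 2.8 Mb, where the block with the centromere point begins. The 5 other blocks without a point lay on chromosomes 1, 2 and 3, with D between -0.98 and -0.61. Most were split from a neighbouring block by a single 100 kb bin, such as 16 to 16.4 Mb of chromosome 1 and 15.3 to 15.9 Mb of chromosome 3. The block at 1.8 to 2.2 Mb of chromosome 2 ended shortly before the block that begins at 2.4 Mb. These blocks are thus not clearly separate from the low D around the points. The block rule was set after the values had been seen, and it fixes a low D within the blocks.

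The next comparison was of the chromosome ends with the rest of the arms. In the first and last 50 kb of the chromosomes, summed over all ends, HTR5 was at 1.09-fold of its input and HTR13 at 0.910-fold, and D was 0.26 (interval 0.25 to 0.26). D 50 to 100 kb from the ends was 0.24, and beyond 10 Mb from the centromere points it was also 0.24, so the summed D at the ends was close to that of the outer arms. After correction for positions already taken these were, in the same order, 0.37, 0.31 and 0.34. Without chromosome 2 the uncorrected D at the ends was 0.32. HTR5 enrichment was 0.18 in the last 10 kb, 0.14 at 10 to 20 kb, 0.09 at 20 to 50 kb and 0.07 at 50 to 100 kb. HTR13 enrichment rose towards the ends as well, from -0.18 at 50 to 100 kb to -0.09 in the last 10 kb. After correction for positions already taken HTR5 was 0.20 in the last 10 kb and 0.27 at 10 to 20 kb. HTR5 at the single ends ranged from -0.07 at the start of chromosome 2 and -0.05 at the end of chromosome 4 to 0.30 at the end of chromosome 3 and 0.33 at the end of chromosome 2. In the same order these were -0.20, -0.14, 0.50 and 0.52 after the correction. Of the 10 ends, 8 had a D whose interval lay above 0, up to 0.57 at the end of chromosome 3. The start of chromosome 4 had a D of -0.01 with an interval that included 0, and a D of 0.04 after the correction. The start of chromosome 2 had a D of -0.83, and 72.6% of its start positions were unmappable. The short arms of chromosomes 2 and 4 carry the nucleolus organizer regions, the arrays of ribosomal RNA genes, near their ends.

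At the scale of 1 kb, 117417 bins held at least 20 reads in each input. D was at least 1 in 16922 of them (14.4%) and at most -1 in 17552 (14.9%). Neighbouring bins are not independent, so no interval is given for these shares. The same rule applied to the inputs gave 1 bin and 11 bins. In the pericentromeres, 61.1% of 18942 bins were HTR13-rich by this rule and 2.21% were HTR5-rich. In the arms, 16.8% of 98475 bins were HTR5-rich and 6.07% were HTR13-rich. These names compare the 2 histones, so an HTR5-rich bin can be poor in HTR13 without HTR5 being above its input. Of the HTR5-rich arm bins, 1288 had HTR5 at 0.5 or higher and HTR13 at -0.5 or lower. The spread of D over bins was 0.90 (SD), against a spread of 0.14 for the log2 ratio of the inputs and a median counting error of 0.11. D had the same sign in reads of the plus strand and of the minus strand in 16919 of the HTR5-rich bins and 17545 of the HTR13-rich bins. These are parts of the same libraries and not replicates, and picking bins by the size of D all but fixed this outcome.

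**Figure D3:**
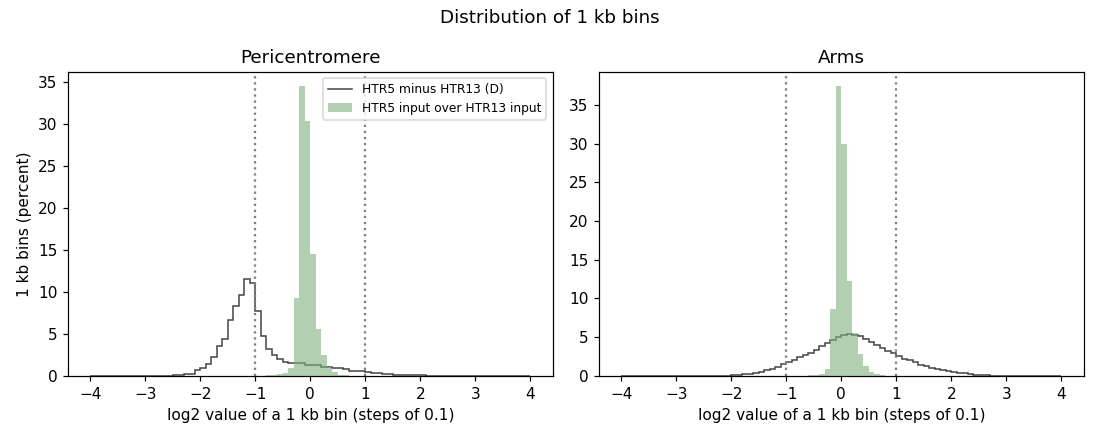
Percent of 1 kb bins by D and by the log2 ratio of the inputs, in steps of 0.1, in the pericentromeres and in the arms. Dotted lines mark -1 and 1. In the pericentromeres 61.1% of bins have a D of at most -1, and in the arms 16.8% have a D of at least 1.

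The length of runs of such bins was measured next. In the arms, HTR5-rich bins formed 9585 runs with a median length of 1 kb, and the longest was 12 kb. In the pericentromeres, HTR13-rich bins formed 2150 runs with a median length of 3 kb and a longest run of 96 kb, and 76.7% of these bins lay in runs of 5 kb or more. HTR13-rich bins in the arms formed 2848 runs with a median of 1 kb and a longest run of 32 kb. Within the arms, 31.3% of HTR13-rich bins and 12.9% of HTR5-rich bins lay in runs of 5 kb or more, although HTR13-rich bins were fewer there. The longer runs of the pericentromeres go with a higher share of HTR13-rich bins, so run lengths of the 2 parts are not directly comparable.

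Bins were also grouped by positions at which none of the libraries had a uniquely placed read, called unmappable here. In arm bins with no unmappable position HTR5 was at 0.04 and HTR13 at -0.13, with D at 0.17. HTR13 enrichment in the arms was higher in bins with more unmappable positions: 0.09 in bins with up to 20%, 0.30 in bins with 20 to 50% and 0.54 in bins with over 50%. HTR5 moved less over the same classes, to -0.09 in the last. D in arm bins with over 50% unmappable positions was -0.63. The size depended on distance: D in such bins was -0.70 at 3 to 5 Mb from the centromere points, -0.45 at 5 to 10 Mb and -0.16 beyond 10 Mb (0.3 Mb of bins), against 0.10, 0.19 and 0.25 in bins without unmappable positions at the same distances. In the pericentromeres, bins without any unmappable position still had HTR13 at 0.43 and HTR5 at -0.20, with D at -0.64.

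**Figure D4:**
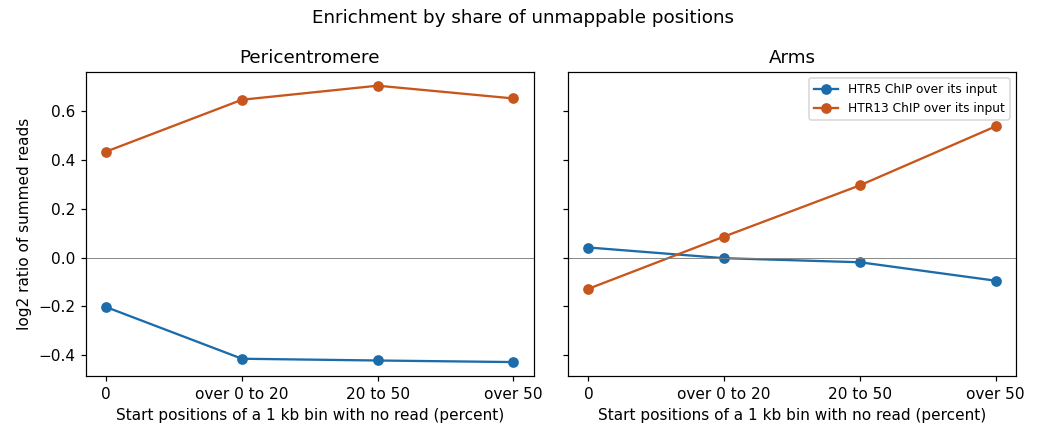
Enrichment over input (log2, summed reads) of HTR5 and HTR13 in 1 kb bins grouped by their share of unmappable start positions in percent. In the arms HTR13 goes from -0.13 to 0.54, and in the pericentromeres it lies at 0.43 or above in every class.

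The inputs were searched for places at which they differed from each other, as a check of the labels. Of 187798 bins of 500 bp, 7 differed by 0.9 or more on the log2 scale, and they formed 2 intervals. On chromosome 4, from 18558001 to 18560000, the HTR5 input was 1.95-fold above the HTR13 input after correction for positions already taken. The interval lay 25 kb from the highest position of the chromosome, and HTR5 is followed by only 12 genes in the gene order of chromosome 4 in TAIR10.1. On chromosome 5, from 3269001 to 3270500, the HTR13 input was 2.68-fold above the HTR5 input. HTR13 is a gene of chromosome 5. The input labelled HTR5 thus held extra reads on the chromosome of HTR5, and the input labelled HTR13 on the chromosome of HTR13.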

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

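The tests on fully mappable bins, after correction for taken positions and on the inputs were chosen after the pattern had been seen, and so were the blocks. HTR5 and HTR13 moved in opposite directions against their inputs in the pericentromeres, the arms, the chromosome ends and the 11 blocks, parts that overlap. With 1 library each, these differences were not tested. D was -0.85 in the pericentromeres and -0.84 in the block on the short arm of chromosome 4, with HTR13 above and HTR5 below its input. The same held in the other blocks, with D at -0.98 (13.2 to 15.9 Mb) and -0.98 (16 to 16.4 Mb) on chromosome 1, -0.61, -0.98, -0.70 and -0.73 on chromosome 2, -1.02 and -0.74 on chromosome 3, -1.07 around the point of chromosome 4 and -1.02 on chromosome 5. D was 0.14 in the arms and 0.26 at the chromosome ends, with HTR5 above and HTR13 below its input. Since each library is scaled to its own total, the summed arm values follow from those of the pericentromeres and are not a separate result.

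Technical explanations were weighed for the opposite enrichment near the centromeres, measured as the difference in D between pericentromeres and arms (-0.98). Repeats that cannot be mapped would leave little difference where every position is mappable, but the difference there was -0.81. Saturation of the collapsed positions would leave little difference after correction for taken positions, but it was -1.35. This outcome was all but fixed. Near the points 27.8% of the HTR5 ChIP positions and 46.0% of the HTR13 ChIP positions were taken. At such values the correction widens the difference. The correction is able to end a difference in other conditions. In a simulation with no true D, unequal depth and saturation alone gave -0.86, and the correction left -0.03. That simulation had 97.7% of the HTR5 ChIP positions near the points taken and 67.5% of the HTR13 ChIP positions, the reverse order of the files. In 3 simulations with over 99% of the HTR5 ChIP positions taken, the correction ended the difference only in part. The files, at 27.8%, lay far below these simulations. At the depth of the files, with 1 shared profile for both ChIPs, saturation alone gave -0.001 before correction. Bins with few taken positions in the inputs were set aside as a test, since the simulated difference of -0.86 stayed at -0.70 in them. A difference between the inputs would have to raise the ratio of the HTR5 to the HTR13 input near the centromeres. That ratio was lower there than in the arms, by a difference of -0.088, which works against the pattern once the inputs are divided out. The inputs themselves thus differed in the same direction as the ChIPs, though far less, and the cause of this was not tested. GC content was not tested, and neither were differences between the lines in the amount or timing of the tagged proteins, so these stay open beside a different distribution of H3.3 and H3.1, which the groups were made to compare.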

How the results depend on the processing

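The correction for taken positions, fully mappable bins and the second rule for centromere points were chosen after the data had been seen. Of 151 alternative values, 0 changed sign, 73 lay within counting error of the value reported (or within 1.5 times of a count) and 78 lay outside it. The 151 include counts of bins, which cannot change sign. They also include settings that cannot move a given summed value, so these totals overstate stability. At this depth counting error is far below the difference between processing choices, so the size of a value is known less well than its interval says. In the order difference in D between pericentromeres and arms, HTR5 and HTR13 enrichment in the pericentromeres, and D at the chromosome ends, the input of the other line gave -1.16, -0.38, 0.62 and 0.24, and the correction for taken positions -1.35, -0.43, 0.73 and 0.37. Without inputs the difference in D was -1.07. Scaling to the median of 10 kb bins gave -0.29 and 0.59 for HTR5 and HTR13 in the pericentromeres and 0.22 at the ends. For the first 3 of these values a pericentromere of 1 Mb gave -1.11, -0.42 and 0.62, fully mappable bins -0.81, -0.23 and 0.51, and centromere points placed by unmappable positions -1.004, -0.31 and 0.56. Leaving out each chromosome in turn gave ranges of -1.01 to -0.95, -0.32 to -0.28, 0.53 to 0.57 and 0.19 to 0.32. A threshold of 0.5 gave 35613 HTR5-rich and 33052 HTR13-rich bins of 1 kb, which follows from the lower threshold. For the other values outside counting error the cause was not tested. Minimums of reads per bin and the reads added act on bins and hardly on summed regions. No paired analysis was possible because each group held 1 library. The GC correction, the mismatch filter and the filter on other alignments were not run.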

Other observations

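The search of the inputs and the reading of the labels from it were chosen after the data had been seen, as were the windows, segments, shuffles, organelle values and the tests at the centromere points below. Outside the blocks and the pericentromeres, the rule of at least 3 neighbouring 10 kb windows gave 16 HTR13-rich segments (D of -0.8 or lower) with a longest length of 50 kb, and 4 HTR5-rich segments (D of 0.8 or higher) of up to 30 kb. In the latter HTR5 lay between -0.17 and 0.19 and HTR13 between -1.27 and -0.68, so they were chiefly poor in HTR13. Many of the HTR13-rich segments lay just outside a pericentromere, such as 12700001 to 12730000 on chromosome 1, whose point is at 14.9 Mb. HTR13 enrichment was still 0.23 at 2 to 3 Mb from the points. The share of unmappable positions in the HTR13-rich segments reached 69.4%, but 1 on chromosome 3, from 21580001 to 21620000, had only 0.080% of them. There HTR5 was at -0.81 and HTR13 at 0.38, with D at -1.19 and a counting error of 0.02. Another on chromosome 2, from 1200001 to 1250000 with the point at 3.6 Mb, had D at -1.19 and 5.23% unmappable positions. The 10 kb window with the highest uncorrected D in the arms lay on chromosome 1, from 26240001 to 26250000. It held 575 HTR13 ChIP reads against 4390 in the HTR13 input, an enrichment of -2.68, while HTR5 was at -0.51 and D at 2.17. After correction for taken positions its D was 2.19, below the 2.33 of the window from 22530001 to 22540000 on chromosome 3. In 3 of the 5 windows with the highest D, HTR5 was itself below its input.

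In the arms HTR5 and HTR13 enrichment were not mirror images at the scale of 1 kb. Across 98475 arm bins of 1 kb they had a Pearson correlation of 0.32 and a Spearman correlation of 0.30. Bins are not independent replicates. Both were at most -0.5 in 10680 arm bins (10.8%), and both were at least 0.5 in 1488 (1.51%). HTR5 was at least 0.5 and HTR13 at most -0.5 in 1288 bins, and 1465 had the opposite. When HTR5 enrichment was shuffled among arm bins with similar input reads, the Pearson correlation was on average 0.10 over 100 shuffles, with 8419 bins low in both, 1547 high in both, and 2618 and 2803 in the opposite classes. A cruder shuffle, of HTR5 ChIP reads over all arm bins with the inputs in place, gave -0.02, with 10758 bins low in both and 4494 high in both. The correlation was thus above both shuffles, but the count low in both was above only the first, and the count high in both was above neither. In 18942 pericentromeric bins the Pearson correlation was 0.21 and the Spearman correlation 0.30. After the same shuffling the Pearson correlation there was 0.02. Before it, 3202 bins (16.9%) had HTR13 at least 0.5 and HTR5 at most -0.5, and 406 (2.14%) had both at most -0.5. After shuffling, these were 4412 and 456, and 5435 and 622 in the cruder shuffle, so both counts were below either shuffle. In bins of 200 bp in the arms, the correlation of HTR5 enrichment with itself was 0.13 at 1 kb and 0.05 at 2 kb, and that of HTR13 was 0.38 and 0.23. In the pericentromeres D correlated with itself at 0.54 over 2 kb and 0.15 over 20 kb.

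The inputs carried a sign of which line they came from. If the labels of the inputs were exchanged (swapped input labels), the excess of the HTR13 input would lie on chromosome 4, but it was the HTR5 input that had its excess on chromosome 4, where HTR5 lies. A candidate explanation of both intervals is an added tagged copy of each gene, which was not tested further.

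Around the centromere points themselves, HTR5 within 0.25 Mb was lower than at 0.5 to 1.5 Mb by a difference of -0.15, whereas HTR13 differed by 0.01. The points are middles of 1 Mb windows, and the other rule moved that of chromosome 4 by -0.5 Mb, more than the 0.25 Mb used here. On chromosome 4 the comparison thus depends on where the point was placed. Without chromosome 1, where HTR5 differed by -0.59, the difference of HTR5 was -0.13, and on chromosome 3 it was 0.03. After correction for taken positions HTR13 was 0.74 at the points and 0.78 at 0.5 to 1.5 Mb. On chromosome 1 HTR13 was lower too, by a difference of -0.28, with 63526 HTR13 input reads in that stretch. Whether unmappable repeats could account for a lower signal at the points was not settled. In fully mappable bins HTR5 was still lower at the points by a difference of -0.091, with a counting error of 0.005, which goes against repeats as the whole cause. The 4 chromosomes with at least 50 such bins differed among themselves, from -0.20 to 0.04, and the 95% t interval of their mean was -0.24 to 0.07, so this does not exclude it. In fully mappable bins HTR13 was higher at the points by 0.058, but over the 5 chromosomes HTR13 differed little with or without the correction, and chromosome 1 had only 6 such bins. The bound written for the HTR13 test alone would have counted for the repeats. The condition that the lower signal must first be seen over all bins was added after the value was known.

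Reads on the organelle genomes were counted as well. In the inputs 98.5% of the mappable chloroplast positions were taken, against 23.0% in the HTR5 ChIP and 28.7% in the HTR13 ChIP. The mitochondrial genome was less even between the ChIP libraries, with 37.4% of its mappable positions taken in the HTR5 ChIP and 69.1% in the HTR13 ChIP. Corrected for taken positions and relative to the nuclear depth of the same library, the chloroplast stood at 8.02 in the HTR5 input, 8.09 in the HTR13 input, 0.525 in the HTR5 ChIP and 0.807 in the HTR13 ChIP. The mitochondrial genome stood at 5.34, 5.39, 0.940 and 2.81. The inputs are close to saturation on both genomes, so their values are rough. On this scale the HTR13 ChIP exceeded the HTR5 ChIP by 1.54-fold on the chloroplast and 2.99-fold on the mitochondrial genome, where the ratio ranged from 2.85 to 3.43 in 12 segments. Only 28.8% of the mitochondrial genome was mappable, and copies of it in the nuclear genome were not separated from it, so these values do not measure background alone.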
